A study of Danio rerio with 6 samples.

How the data were processed

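RNA was measured in 6 libraries of zebrafish larvae, 3 treated with 4-octyl itaconate and 3 controls, after enrichment of messenger RNA per the labels' protocols. The signal values deposited by the authors were normalized counts per gene, meaning gene counts divided by 1 factor per library. Per the submitters' processing notes, bcl2fastq 2.20.0.422, fastp 0.23.2, STAR 2.7.10a, Salmon 1.9.0 and DESeq2 (no version) were used with build GRCz11. The notes give neither the role of each tool nor any filter, and they do not say how reads shared between near-identical genes, or between a gene and its antisense partner, were counted. The table paired 24470 Ensembl gene IDs with names, of which 77 had none, and 379 symbols stood on more than 1 gene ID. No genome or annotation of the build was at hand, so no coordinates are given and gene length and GC content were not checked.

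Whole reads were recovered by dividing each library's values by its smallest step. In 100% of values the result lay within 0.01 of a whole number, with a largest deviation of 0.000787. Median-of-ratios factors recomputed from those reads were 1.12 to 1.135 times the deposited ones, a nearly constant ratio. A floor of 3 reads over a group corresponded to 1.06 normalized counts in treated and 1.15 in control libraries; floors cover counting error only.

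Genes with a mean of at least 10 normalized counts over the 6 libraries were tested, 20352 in all, and 4118 were left out. Values were tested as log2(normalized count + 1) with limma 3.58.1 in R 4.3.3 (two-sided moderated test, intensity trend, no covariate) and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Log2 fold changes are treated minus control on that scale, which understates changes of low genes, and folds are ratios of group means. Single genes in groups of 3 cannot go below an exact permutation p of 0.1, so the limma p-values rest on the spread shared across genes.

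Before the data were examined, 33 gene lists were fixed, with 1248 members written, 1198 matched to the table and 1170 tested. Lists were tested with limma's camera (preset correlation 0.01, two-sided, Benjamini-Hochberg adjustment over the 33 lists), and again with the correlation estimated from the data and with fry. Camera compares a list with all other genes, while fry asks whether its genes move, on balance, one way. The rule for named genes, also fixed then, took the genes of the study's subject and the 10 largest rises and falls among named genes past the threshold with a mean of at least 50 normalized counts in the higher group and no overlap between groups. It also took up to 4 members with the smallest p in each list. Where a group was at 0 in all its libraries, the fold is a bound against the floor.

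The tests were tried on simulated counts for the same 20352 genes. At an adjusted p of 0.05, limma recovered 17% of 100 genes changed 2-fold and 79% of 100 genes changed 4-fold, and 8 of its 104 calls (7.69%) were false. By edgeR these were 18% and 79%, with 9 of 106 calls (8.49%) false. Camera called a list of 30 raised genes up (adjusted p = 2.9e-36) and none of 30 unchanged lists. Simulated genes were drawn independently of each other, and far fewer were changed than in the data. The trial therefore does not show how camera behaves with correlated genes, nor the rates of recovery and false calls in these data.

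Alternatives covered the pseudocount, the filter on low values, the scaling, the limma options, a block for the replicate number, each library left out in turn, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.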

Results

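Messenger RNA was sequenced from zebrafish larvae of the line Tg(Brn3C:mGFP), in which a membrane-bound green fluorescent protein marks hair cells. The treated group held 3 libraries from larvae kept in 2.5 µM 4-octyl itaconate, a cell-permeable ester of itaconate, for 48 h starting at 3 days post fertilization. The other group held 3 control libraries, and both groups were collected at 5 days. The vehicle of the controls and the number of larvae, clutches or cultures behind each library are not given in the sources used here, so p-values measure only the spread between these samples, which may be technical. The deposited values were normalized counts, from which 19754599, 18017272 and 23507208 reads were recovered for treated replicates 1, 2 and 3. Control replicates 1, 2 and 3 gave 21096650, 16516882 and 14763897 reads. Log2 values of the tested genes correlated at 0.928 to 0.972 (Pearson, across genes) between treated libraries, at 0.971 to 0.974 between control libraries and at 0.672 to 0.731 between groups. The first principal component held 84.6% of the variance and separated the groups, and the second held 6.83% and set treated replicate 1 apart from the other libraries.

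The series concerns the Irg1l and itaconate axis, neuromast size, metabolism and Yap signalling, and its design implies 1 comparison, larvae given 4-octyl itaconate against control larvae. Treated larvae carried many more transcripts of digestive organs, skeletal muscle, blood and skin than control larvae, and fewer of neurons, the eye and the mitochondrial genome. Liver markers rose with a median log2 fold change of 4.65 (30 of 31 members rose), pancreas and intestine markers with 5.33 (34 of 35), and skeletal muscle markers with 2.96 (35 of 37). Neuron and glia markers fell with a median of -2.71 (27 of 33 members fell), eye markers with -2.23 (32 of 46), and mitochondrially encoded genes with -2.34 (13 of 13). Of 20352 genes tested with limma, 14098 (69.3%) passed an adjusted p of 0.05, 7115 higher and 6983 lower in treated larvae, and 11258 of these changed by a log2 fold change of at least 1. In 74.1% of tested genes all 3 libraries of one group lay above all 3 of the other, against 10% by chance.

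The protease genes prss59.1 and prss59.2 rose 560-fold and 507-fold, prss59.2 from 128 ± 49.1 to 64973 ± 23922 normalized counts (mean ± SD, n = 3 per group; limma adjusted p = 5.33e-07). The other genes among the 10 largest rises were the digestive enzyme genes ctrb1, ela2, ela3l, cpa5, cpa1, prss1 and cel.1 and the zymogen granule gene sycn.2, with log2 fold changes of 7.70 to 8.58. Among the largest falls, the opsin gene parapinopsinb fell from 618 ± 155 to 8.79 ± 2.87, and the retinal calcium channel gene cacna1fb from 1125 ± 401 to 26.2 ± 29.9 (limma adjusted p = 1.81e-06 and 8.45e-05). The 10 largest falls also held cabp2a, ccdc24, slc1a8a, lrit1a, ankrd6a and the eye field transcription factor gene rx3, with log2 fold changes of -6.24 to -5.59. Treated replicate 1 held more of cabp2a, slc1a8a, lrit1a, ankrd6a, rx3 and cacna1fb than the other treated libraries. Without it their log2 fold changes were -7.71, -6.79, -7.13, -7.28, -7.15 and -6.82. One of the gene IDs named evx1, an interneuron transcription factor gene, was at 0 in all 3 treated libraries and at 106 ± 30.8 in controls, at least 99.8-fold lower against a floor of 3 reads over the group. The other gene ID named evx1 stood at 38.4 ± 17.9 in treated and 35.1 ± 15.0 in control larvae. Likewise 1 gene ID named actc1a, a cardiac actin gene, stood at 0 in treated replicates 1 and 3 and fell by 7.70 on the log2 scale, while the other rose 27.6-fold. Reads can be divided between gene IDs that share a symbol, so the falls of evx1 and actc1a are uncertain.

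Transcripts of irg1l, a zebrafish counterpart of the gene for the itaconate-producing enzyme, rose 9.92-fold, from 37.4 ± 22.8 to 371 ± 208 normalized counts (log2 fold change 3.25, SE 0.52, limma adjusted p = 0.000556), and 15.2-fold without control replicate 3. The related gene acod1 stood at 270.0 normalized counts in treated replicate 2 and at 17.9 and 18.1 in treated replicates 1 and 3, against 5.56 to 15.5 in controls. Its log2 fold change of 2.34 (SE 0.98) did not pass the limma test (adjusted p = 0.0583), and without treated replicate 2 it was 1.06 (adjusted p = 0.165). It passed with upper-quartile scaling (adjusted p = 0.0376), with arrayWeights (0.0345) and by edgeR on recovered reads (log2 fold change 3.57, adjusted p = 0.0215). Leaving out treated replicate 1 or 3 instead gave adjusted p of 0.0169 and 0.0395, with log2 fold changes of 2.98 and 2.97.

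Yap and Taz transcripts were both higher in treated larvae. The Taz gene wwtr1 rose 12.3-fold, from 15.7 ± 4.06 to 193 ± 35.8, and yap1 rose 1.45-fold, from 1059 ± 71.9 to 1534 ± 111 (limma adjusted p = 1.44e-05 and 0.00651). Among target genes often used to read Yap activity, ccn1, ccn2a and ccn2b rose by log2 fold changes of 0.76 (SE 0.20), 0.66 (SE 0.18) and 3.85 (SE 0.41), with limma adjusted p of 0.00745, 0.00874 and 4.81e-05. Values for ankrd1a and amotl2a did not pass (log2 fold changes 0.52 and -0.10, limma adjusted p = 0.083 and 0.546), although ankrd1a passed with upper-quartile scaling (0.84, adjusted p = 0.0114) and amotl2a was above 0 after upper-quartile scaling and quantile normalization. Of 34 tested Yap/Taz-Tead targets, 21 rose and 2, fjx1 and inhbab, fell, and 11 did not pass; the median log2 fold change was 0.85, and camera gave an adjusted p of 0.00113, against an adjusted p of 0.383 with an estimated correlation. The members with the smallest p were tagln, an actin-binding protein of contractile cells, tgm2b, fstl1a and nt5e, which rose 7.78-fold, 5.56-fold, 4.34-fold and 5.12-fold. Cytoskeleton and matrix genes moved with them: 36 of 41 rose and 3 fell, col4a1 21.1-fold, with a median of 2.03 (camera adjusted p = 1.94e-10, and 0.281 with an estimated correlation). Skin and ionocyte markers also rose, by a median of 1.63, while neuron and glia markers fell. In the 25 Hippo pathway and Tead components, 12 rose, among them sav1 3.26-fold, and 8 fell, among them dchs1b 6.31-fold and tead1b 3.80-fold. The other Tead genes of the list, tead1a, tead3a and tead3b, rose 4.29-fold, 4.25-fold and 5.12-fold (limma adjusted p of 0.000411 to 0.00203). As a whole the list did not pass (median 0.53, camera adjusted p = 0.312).

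**Figure D1:**
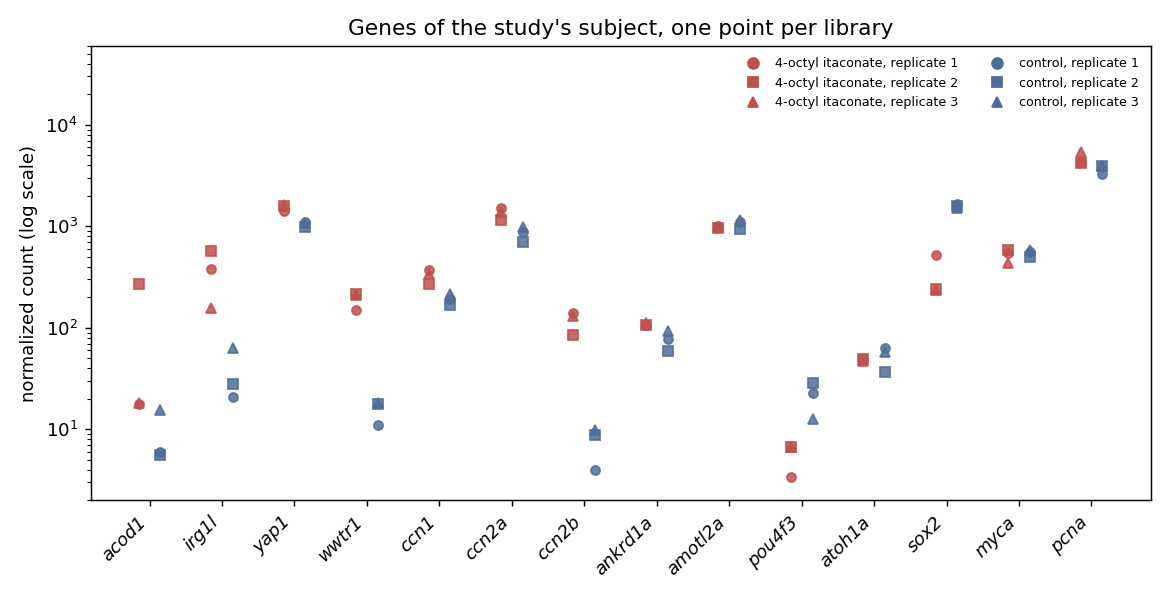
Normalized count (y axis, log scale) of the genes of the study's subject in each library, with treated libraries in red and control libraries in blue and 1 point per library. Treated libraries hold 157 to 573 normalized counts of irg1l and control libraries 21.1 to 63.4, and 1 treated library holds 270.0 counts of acod1.

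Hair cell genes went both ways. The calcium-binding protein genes s100t and pvalb8 rose 7.81-fold and 9.88-fold. The transcription factor gene barhl1a and the otoferlin gene otofa, needed for synaptic vesicle release in hair cells, fell 11.5-fold and 7.80-fold. Limma adjusted p for these genes was 5.43e-06 to 1.20e-05. The other otoferlin gene, otofb, rose 7.41-fold, from 76.6 ± 66.4 to 568 ± 98.0 normalized counts (limma adjusted p = 0.000394). Expression of pou4f3, a hair cell transcription factor gene, was low, at 12.7 to 28.9 normalized counts in control and 3.36 to 6.75 in treated libraries, and fell (log2 fold change -1.75, SE 0.53, limma adjusted p = 0.016); without control replicate 1 or 2 its adjusted p was 0.0578 and 0.0674. That of atoh1a did not pass (log2 fold change -0.08, SE 0.30, limma adjusted p = 0.832). Of 36 hair cell genes, 14 rose, 12 fell and 10 did not pass, and the list had a median of -0.07 (camera adjusted p = 0.908), which lay between -0.46 and 0.24 over the scalings tried. Its direction was down by camera and up by fry, and neither passed. In the same larvae, neuron and glia markers had a median of -2.71 and eye markers of -2.23. These libraries do not show in which cells a gene of the hair cell list rose or fell.

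Neuromast support and mantle cell genes included 22 that rose and 11 that fell of 36 (23 and 11 when adjusted over the list alone), with a median of 1.17 and no call by camera (adjusted p = 0.115). The keratin gene krt15, the glutathione peroxidase gene gpx1b and agr2, which serves mucus-secreting cells, rose 7.07-fold, 8.20-fold and 10.4-fold. The progenitor gene sox2 fell from 1597 ± 78.2 to 333 ± 163, and the connexin gene cx43, also a glial marker, fell 3.55-fold (limma adjusted p = 9.74e-05 and 4.59e-06). In the lateral line signalling list (Fgf, Wnt and Notch), 23 of 39 members fell and 6 rose, with a median of -0.69 (camera adjusted p = 0.0241, and 0.505 with an estimated correlation; 0.112 after quantile normalization). The Wnt targets sp5l and lef1 fell 21.3-fold and 3.19-fold and the Notch target her4.4 fell 3.07-fold, whereas the Fgf receptor gene fgfr1b rose 14.8-fold. Neuron and glia markers fell in the same larvae, from 1.05% ± 0.0422 to 0.174% ± 0.0234 of all reads (SD, n = 3 per group). The lateral line was not measured apart from the brain or other tissue. The growth and replication genes myca and pcna had log2 fold changes of -0.08 (SE 0.17) and 0.32 (SE 0.16), which did not pass (limma adjusted p = 0.686 and 0.0969); that of pcna passed without treated replicate 1 (adjusted p = 0.0395), with upper-quartile scaling (0.00565), quantile normalization (0.0274) and arrayWeights (0.0195).

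Glycolytic genes went both ways. The genes gapdh, aldoab, eno3 and pgam2 rose 19.6-fold, 14.7-fold, 9.75-fold and 14.7-fold, of which eno3 and pgam2 are the muscle forms of enolase and phosphoglycerate mutase (limma adjusted p of 5.96e-07 to 1.28e-06). Their counterparts eno2, pgam1b and aldocb, of which eno2 and aldocb are known from the nervous system, fell by 2.58, 1.92 and 2.34 on the log2 scale. In all, 16 of 39 rose and 12 fell, with a median of 0.10 (camera adjusted p = 0.337), and over the scalings tried the median lay between -0.01 and 0.42. The falls of eno2, pgam1b and aldocb, like other genes outside the naming rule, were picked out after their values were seen. Skeletal muscle markers took 14.2% ± 0.618 of reads in treated and 2.16% ± 0.0351 in control libraries, with tpma, a fast muscle tropomyosin gene, 32.7-fold and tnni2a.4, smyhc1 and myhz2 15.9-fold to 18.4-fold higher.

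Nuclear genes of oxidative phosphorylation rose almost as a block while the mitochondrial genome's own transcripts fell. Of 79 nuclear genes, 77 rose, cox4i2 fell and uqcrh, at a log2 fold change of 0.09, did not pass; ndufs7, atp5f1d and uqcrc2a rose 3.90-fold, 3.81-fold and 4.17-fold, and cox8b rose by 3.30 on the log2 scale. Their median log2 fold change was 1.34 (camera adjusted p = 1.57e-15, and 0.311 with an estimated correlation). All 13 mitochondrially encoded genes fell, mt-nd6 9.77-fold and mt-nd5, mt-nd2 and mt-nd4 by 6.05-fold, 6.39-fold and 5.65-fold (camera adjusted p = 2.16e-05, and 0.453 with an estimated correlation). They took 5.21% ± 0.426 of reads in treated and 25.1% ± 3.34 in control libraries (SD, n = 3 per group). Genes of the tricarboxylic acid cycle rose in 22 of 33 cases and fell in 4 (23 and 4 when adjusted over the list alone), with a median of 0.86 (camera adjusted p = 0.000611, and 0.472 with an estimated correlation). The members suclg1, aco1, sdhc and mdh2 rose 4.58-fold, 7.11-fold, 3.43-fold and 2.63-fold, while ogdhl fell by 3.63 on the log2 scale. Muscle and liver markers rose in the same larvae and neuron markers fell. Of 75 genes of cytosolic ribosomal proteins, 69 rose and 1 fell (71 and 1 when adjusted over the list alone), rps9 4.26-fold, with a median of 1.18 (camera adjusted p = 9.96e-12, and 0.472 with an estimated correlation; 0.0579 after quantile normalization). Over the scalings tried that median was as low as 0.15, against 1.24 for nuclear oxidative phosphorylation genes.

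**Figure D2:**
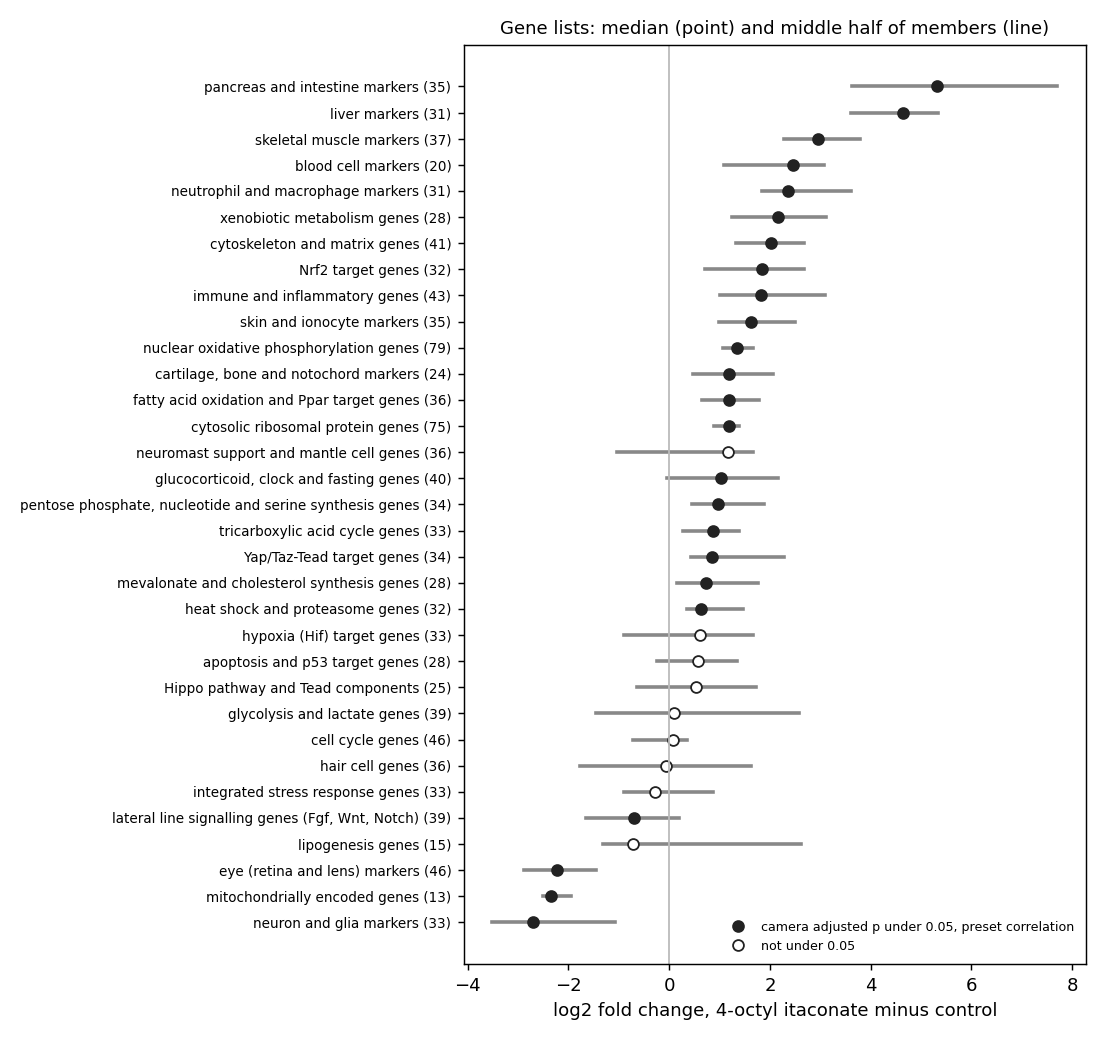
Median log2 fold change (point) and the range between the quartiles of the members (line) of each gene list, treated minus control, with the number of tested members in brackets; filled points passed camera at an adjusted p of 0.05 with the preset correlation. Pancreas and intestine markers lie highest, at 5.33, and neuron and glia markers lowest, at -2.71.

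Of 4 other metabolic lists, 3 passed camera up and lipogenesis did not. Genes of fatty acid oxidation and Ppar targets rose in 26 of 36 cases and fell in 3 (median 1.19, camera adjusted p = 9.69e-05, and 0.355 with an estimated correlation), and the members with the smallest p, the fatty acid binding protein genes fabp2 and fabp1b.1 of intestine and liver, rose 14.8-fold and 24.3-fold. Of the pentose phosphate, nucleotide and serine synthesis genes, 24 of 34 rose and 3 fell (median 0.97, camera adjusted p = 0.00013, and 0.505 with an estimated correlation), paics 10.9-fold and mthfd1l 27.4-fold. In mevalonate and cholesterol synthesis, 12 of 28 rose and 1, ggps1, fell (11 and 1 when adjusted over the list alone; median 0.73). Its camera adjusted p was 0.0231, 0.0713 and 0.0671 without treated replicate 2 or 3, 0.0856 by fry and 0.666 with an estimated correlation. Lipogenesis genes divided into 7 that rose, such as dgat2, for triglyceride synthesis, 123-fold (209-fold without control replicate 3), and 8 that fell, such as fasn, for fatty acid synthesis, which fell by 1.77 on the log2 scale. Their median was -0.72, their mean 0.83 and the camera direction up, with no call (adjusted p = 0.905; by fry 0.026). Liver markers in the same larvae took 2.99% ± 0.0575 of reads against 0.0943% ± 0.012 in controls, and pancreas and intestine markers 1.73% ± 0.479 against 0.0403% ± 0.00642. Of the liver markers, apoa2, apoa1a, apoa1b and apoa4b.1, which encode apolipoproteins, rose 115-fold, 51.4-fold, 43.1-fold and 27.9-fold; the list gave a camera adjusted p of 6.31e-15, and 0.281 with an estimated correlation.

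Detoxification genes known to respond to Nrf2, a transcription factor that itaconate derivatives activate, rose in 25 of 32 cases and fell in 2, tkta and slc7a11. The glutathione transferase genes gsta.1 and gstp1 rose 9.39-fold and 7.17-fold, the quinone reductase gene nqo1 6.19-fold and cbr1l 6.25-fold (limma adjusted p of 2.28e-06 to 3.29e-06), while gclc and gclm, for glutathione synthesis, had log2 fold changes of 0.01 and 0.21 and did not pass. The list median was 1.84 (camera adjusted p = 9.99e-07, and 0.281 with an estimated correlation). Xenobiotic metabolism genes rose in 21 of 28 cases and fell in 2 (22 and 2 when adjusted over the list alone; median 2.16, camera adjusted p = 2.62e-05, and 0.281 with an estimated correlation), the drug pump gene abcg2a 21.1-fold and cyp3a65 10.1-fold. Heat shock and proteasome genes rose in 18 of 32 cases and fell in 2 (median 0.64, camera adjusted p = 0.000638, and 0.281 with an estimated correlation), hspb1 6.22-fold and hsp90aa1.1 5.93-fold. Glucocorticoid, clock and fasting genes rose in 20 of 40 cases and fell in 5 (median 1.02, camera adjusted p = 0.00819, and 0.281 with an estimated correlation), with pck1 and g6pca.2, for glucose production by the liver, 40.4-fold and 16.3-fold and klf9 16.4-fold higher. Liver and intestine markers, which come from organs that express many of these genes, rose in the same larvae by medians of 4.65 and, with pancreas, 5.33.

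Immune genes were mostly higher in treated larvae. Of 43 immune and inflammatory genes, 29 rose and 3 fell (median 1.82, camera adjusted p = 0.000198, and 0.472 with an estimated correlation), but hp, c3a.1 and crp2, which rose 37.8-fold, 56.7-fold and 52.6-fold, encode plasma proteins made by the liver, and hp and crp2 are symbols carried by more than 1 gene ID. The fold of crp2 was 134 without control replicate 3, and that of c3a.1 was 37.6 without treated replicate 2. Of the 43 members, 5 are also in another list. Beyond the plasma proteins, stat3 rose 8.23-fold. Neutrophil and macrophage markers rose in 25 of 31 cases and fell in 1 (26 and 1 when adjusted over the list alone; median 2.36, camera adjusted p = 6.08e-07, and 0.281 with an estimated correlation). The lysozyme gene lyz rose 19.7-fold and npsn, of neutrophils, 8.63-fold, and cpa5, the member with the smallest p, is also a pancreatic gene. Blood cell markers rose in 15 of 20 cases and fell in 1 (median 2.46, camera adjusted p = 0.000611, and 0.472 with an estimated correlation), with the globin genes hbbe1.1 and hbae3 9.66-fold and 8.35-fold higher.

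Camera passed none of the lists of the integrated stress response, cell cycle, apoptosis and hypoxia. Integrated stress response genes rose in 13 of 33 cases, pck2 9.51-fold, and fell in 11, vldlr 5.23-fold; the median was -0.28, the mean 0.33 and the camera direction up, with no call (adjusted p = 0.808). Over the scalings tried that median lay between -0.38 and 0.05. Cell cycle genes fell in 14 of 46 cases, the mitotic genes cenpe 3.49-fold and ttk 3.36-fold, and rose in 8 (13 and 8 when adjusted over the list alone); the median was 0.07, the mean -0.15 and the camera direction down, with no call (adjusted p = 0.607; by fry 0.0311, down). Over the scalings tried that median lay between -0.03 and 0.39. Apoptosis and p53 target genes rose in 14 of 28 cases, ccng1 2.60-fold, and fell in 2, one of them bbc3 (median 0.58, camera adjusted p = 0.081). That list passed without treated replicate 3 (adjusted p = 0.0385), after quantile normalization (0.0348) and by fry (0.00971). The hypoxia list held targets and also genes of the hypoxia-inducible factors themselves, such as epas1a. In it, 13 of 33 genes rose, epas1a 7.95-fold and p4ha1a 5.78-fold, and 7 fell, kdm3b 6.74-fold (median 0.60, camera adjusted p = 0.253).

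**Figure D3:**
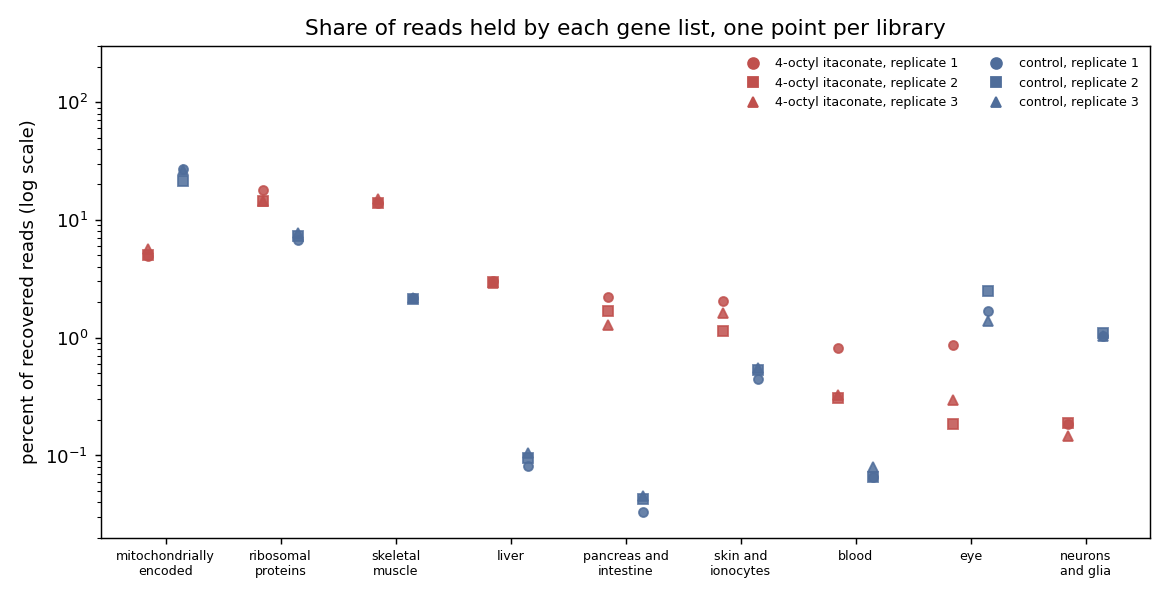
Percent of recovered reads (y axis, log scale) held by each gene list in each library, with treated libraries in red and control libraries in blue and 1 point per library. Mitochondrially encoded genes take 4.90% to 5.70% of reads in treated and 21.2% to 27.2% in control libraries, and liver markers 2.94% to 3.05% against 0.082% to 0.106%.

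Eye markers fell as a list by camera. The members with the smallest p included crx, a photoreceptor transcription factor gene, which fell 14.0-fold, and prph2b and pde6c, which fell 10.8-fold and 7.98-fold (32 of 46 members fell and 1 rose, 33 and 1 when adjusted over the list alone; camera adjusted p = 2.16e-05, and 0.505 with an estimated correlation). Eye markers took 0.868% of reads in treated replicate 1 and 0.184% and 0.295% in treated replicates 2 and 3, against 1.40% to 2.48% in controls. Among neuron and glia markers (28 fell when adjusted over the list alone), the cholinergic gene chata fell by 3.59 on the log2 scale, the synaptic vesicle gene syt1a 16.1-fold and the glycine transporter gene slc6a5 11.5-fold (camera adjusted p = 1.13e-08, and 0.281 with an estimated correlation). Skin and ionocyte markers rose in 30 of 35 cases and fell in 3, the calcium channel gene trpv6 26.1-fold and icn2 11.6-fold (camera adjusted p = 1.06e-06, and 0.368 with an estimated correlation). Cartilage, bone and notochord markers rose in 15 of 24 cases and fell in 1, col10a1a by 3.47 on the log2 scale (median 1.19, camera adjusted p = 0.000653, and 0.383 with an estimated correlation). Camera gave adjusted p of 4.91e-14 for skeletal muscle and 6.75e-14 for pancreas and intestine markers, and 0.281 for both with an estimated correlation.

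Over the 33 lists, camera with its preset correlation passed 24, 20 up and 4 down, and with an estimated correlation none passed; 4 then had an unadjusted p under 0.05, and fry passed 29. Where no second count is given, the counts adjusted over the list alone equalled those over all genes tested.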

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

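Scaling to equal read totals, and edgeR and DESeq2 for named genes, were chosen after seeing the data. Over all settings, 11595 to 15269 genes passed (5502 to 8493 higher, 5693 to 7551 lower, 8745 to 12354 with a log2 fold change of at least 1), each count within 1.5 times its reported value. Without single libraries, 12583 to 14873 passed. On recovered reads, edgeR called 14035 genes (13647 shared with limma) and DESeq2 14629. Upper-quartile scaling moved the median log2 fold change of all genes to 0.33 and the share of calls that were higher from 50.5% to 59.9%. Same-numbered libraries deviated from their group means with correlations of -0.0574 to 0.0497, and not every library correlated best with its own number. No pairing by number was thus seen, which does not exclude a shared clutch or day. With a replicate block, 13679 genes passed. Of 3198 values of 160 named genes, 3178 kept direction and side of the threshold, 2 no longer passed, 10 newly passed and 8 changed sign; of 627 list values these numbers were 582, 29, 8 and 8. Values that changed sign were those of amotl2a (0.22 by upper quartile, 0.28 by quantile), myca (0.24, 0.27; -0.17 to 0.050 without single libraries, turned without treated replicate 3) and atoh1a (0.24 by upper quartile; -0.31 to 0.073, turned without control replicate 1 or 3). Camera with an estimated correlation passed 0 lists (4 at an unadjusted p under 0.05; fry 29), with adjusted p of 0.311 for nuclear oxidative phosphorylation, 0.472 for the tricarboxylic acid cycle, 0.383 for Yap targets and 0.505 for lateral line signalling (0.112 by quantile; 0.00575 to 0.505 over its settings). Fry newly passed glycolysis (9.39e-05), Hippo components (0.0249), support cell genes (0.0399), apoptosis (0.00971), cell cycle (0.0311) and lipogenesis (0.026), did not pass mevalonate synthesis (0.0856), and turned hair cell genes (0.897; 0.874 to 0.983 without single libraries, turned without treated replicate 2, 0.983, or control replicate 2, 0.952). Adjusted p with the direction turned were 0.906 (upper quartile) and 0.624 (quantile) for cell cycle, 0.913 (upper quartile) for lipogenesis and 0.944 (arrayWeights) for the integrated stress response (0.532 to 0.887 without single libraries, turned without treated replicate 1). The cause was not tested. Camera has no robust option, so no list value exists for that setting.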

Other observations

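The genes, gene families and transcript classes of these first paragraphs were chosen after their values were seen, as were all tests of explanations below except that on small housekeeping subunits and the splits of the libraries. The pituitary hormone genes gh1, prl and pomca rose, with gh1, for growth hormone, at 378 ± 149 normalized counts in treated and 4.43 ± 1.60 in control larvae (n = 3 per group), and prl and pomca higher by log2 fold changes of 3.84 and 5.01. Insulin (ins) transcripts had a log2 fold change of 4.43. The neuropeptide genes oxt, crhb and npy fell, with log2 fold changes of -3.19, -3.04 and -2.53, as did gad2, for GABA synthesis, and tph2, for serotonin synthesis, with log2 fold changes of -3.86 and -2.01. The pigment cell genes tyr, pmela and mitfa rose, tyr from 20.8 ± 5.83 to 729 ± 307 and the others by log2 fold changes of 2.12 and 1.83 (limma adjusted p under 0.05 for each gene named here). These genes were not tested as groups.

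Of 230 gene families grouped by symbol, 57 passed camera, 29 up and 28 down, and none with an estimated correlation (lowest adjusted p = 0.531). Among cytochrome P450 genes (cyp), 54 of 77 rose and 4 fell, and among UDP-glucuronosyltransferase genes (ugt) 19 of 24 rose. Protocadherin genes (pcdh) fell in 33 of 49 cases and rose in 2, and glutamate receptor genes (grin) fell in 11 of 13. The medians of these families kept their sign over the scalings tried. Hox genes of groups 1 to 8 fell in 19 of 25 cases and rose in 1, whereas of groups 12 and 13, expressed toward the tail, 7 of 9 rose, hoxb13a 16.0-fold. Over groups 9 to 13 together, 7 of 22 rose and 2 fell. Among long intergenic noncoding RNAs, 161 of 337 fell and 69 rose, with a median of -0.97.

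Markers of digestive organs, muscle, blood and skin were higher and those of neurons and the eye lower in treated larvae. A smaller neural share alone would raise other tissues alike, but the median of pancreas and intestine markers lay 3.7 above that of skin markers (95% bootstrap interval 2.41 to 4.75, 10000 resamples). Intervals here and in the paragraphs below come from resampling the genes of a list as if they were independent. They leave out the spread between libraries, and they are too narrow where genes of a list move together. Controls at an earlier stage alone would leave late phototransduction genes higher in treated larvae, and their median was -1.94 (-2.59 to -1.49). These genes overlap the eye markers, whose fall had been seen, so this was no independent test. Control libraries made from anterior tissue only would leave Hox genes of groups 9 to 13 higher in treated larvae, and their median of 0.10 (-0.26 to 1.12) decided nothing; a comparison with liver markers set after that value was seen (-4.55) is given no weight. Anterior or otherwise uneven tissue in the controls, a mix-up of all libraries of a group and the treatment itself all stay open and may act together. A difference in stage that acts with any of these stays open too, since only stage alone was looked at.

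Mitochondrially encoded genes were lower and nuclear oxidative phosphorylation genes higher in treated larvae. If a few abundant genes had displaced all others, nuclear genes of this pathway would have moved like all tested genes, but their median lay 1.33 above (1.17 to 1.43). A lower yield of short housekeeping transcripts in controls was predicted to raise small subunits of other complexes by at least 0.5 of the nuclear median. Their median lay -0.737 from that mark (-0.989 to -0.358), so these subunits did not rise as far. Gene lengths were not checked, and a difference in tissue makeup could move these subunits too. The test therefore does not decide on a loss of short transcripts. Cytosolic ribosomal protein genes (69 of 75 rose, median 1.18, but as low as 0.15 over the scalings tried) and the proteasome family psma (10 of 10 rose) go with such a loss, which stays open. A difference in tissue makeup or RNA handling and an effect of itaconate on mitochondria may each remain, and neither was tested further.

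Yap/Taz-Tead targets were higher in treated larvae. Their median minus that of skin and ionocyte markers was -0.784 (-1.48 to 0.21), so a rise beyond that of skin markers was not shown. Both medians were known when this comparison was set, so it is no independent test of a larger share of non-neural tissue, which stays open. An effect of itaconate on Yap signalling stays open, since these libraries do not separate expression within a tissue from the amount of that tissue.

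With 6 libraries there are 10 splits into 3 and 3, too few for a share under 0.05. In each of the 5 results counted, 1 of the 10 splits, the real one, gave a count as large. The real split gave 14098 genes past the threshold, 7115 higher, 6983 lower and 11258 with a log2 fold change of at least 1, and the highest other split gave 0 of each. For gene lists the real split gave 24 and the highest other 22. Every other split puts treated and control libraries into the same group, so the difference between them becomes spread within groups. A low count of genes was therefore assured, and the counts do not tell the treatment from chance. Part of that difference also remains between such groups, so lists can pass there.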
